A study of Mus musculus with 12 samples.

How the data were processed

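The data are RNA-seq gene counts from perigonadal white adipose tissue, the visceral fat pad around the gonads, of C57BL/6 mice aged 9 weeks. The mice carried either intact Cdk7 (wild type, called wt) or an adipose-specific knockout of Cdk7 (called ko), and received saline or CL for 7 days. The labels give the drug only as CL, the abbreviation used in this field for a beta-3-adrenergic agonist. Tissue was taken at zeitgeber time 9. Each library was made from RNA of 2 mice, 250 ng from each, pooled to 500 ng. There were 12 libraries in 4 groups of 3, so that 6 mice stood behind each group and the p-values measure the spread between pools of 2 mice.

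Groups were taken from the sample titles, which name genotype and treatment. A separate genotype characteristic in the labels follows the treatment instead and contradicts 6 of the 12 titles. The series design describes both genotypes under both treatments, which only the titles provide. The level of Cdk7 in each library was used to check the titles and not to assign groups.

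The deposited files hold raw counts per gene, which the authors made with STAR and HTSeq on the mouse genome GRCm38 according to the submitters' processing notes. Tool versions and the annotation release are not given in the sources used here. The file names state reverse-strand counting. Each file lists 53379 Ensembl gene identifiers and 5 summary lines for reads that HTSeq did not assign to a gene. Of the identifiers, 53274 were matched to symbols and coordinates of GENCODE M21, an annotation of GRCm38, and 105 were not. The summary lines held 12.5% to 17.2% of all counted reads in a library (median 13.4%) and were left out of library sizes and tests. HTSeq leaves out reads that match more than 1 place or more than 1 overlapping gene, so genes with near-identical copies or same-strand overlaps are undercounted. Cpt1b has 0 counts in every library. In GENCODE M21 a second gene, Gm44502, covers it on the same strand of chromosome 15, but the count files do not list Gm44502, so the cause of the 0 counts is open. Other genes from the lists below also have 0 counts in total, among them Cox4i1, Itgam, Igkc, Rpl13, Irf8, Spg7, Per3 and Gbp4. The mitochondrial genes mt-Co2 and mt-Co3 have 1 count each in total. Only 7 of the 13 mitochondrially encoded messenger RNAs could be tested.

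Depth was 21892817 to 27985019 gene counts per library, with 20239 to 22121 genes detected. The 3 pairs of libraries within each group, 12 in all, were compared by a chi-square test of their counts. The chi-square per degree of freedom was 7.44 to 60.3, so that no library repeats another of its group within sampling noise.

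Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Genes were kept by its filterByExpr function with the group and a minimum count of 10, which left 16554 genes. Library sizes were scaled by TMM, a trimmed mean of log ratios between libraries. All 12 libraries entered 1 model with 1 mean per group and no covariate, which leaves 8 residual degrees of freedom. The common biological coefficient of variation was 11.5%. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Log2 fold changes are given with standard errors, computed as the absolute log2 fold change over the square root of the F statistic of its test. For genes with counts near 0 these are only approximate. Levels are given as CPM, counts scaled to a common library total after TMM, with the standard deviation. The 5 comparisons were CL against saline in each genotype, ko against wt under each treatment, and the difference between the CL responses of the genotypes.

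Before the data were examined, 42 gene lists were written for pathways, complexes, cell types and technical signals. Each was tested in every comparison with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison. The epididymis and testis list had only 2 genes past the filter and was not tested, which left 41 lists. Camera with a correlation estimated from the data and fry, a rotation test of whether a list moves one way on balance, were alternatives. Beside the number of members called over all genes, the number called when adjusted over the list alone is given where it differs.

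Genes named in the text were chosen by a rule written before the data were examined. For each comparison these were the 10 largest increases and 10 largest decreases among called protein-coding genes. They needed a mean of at least 5 CPM in 1 of the groups compared and, in the pairwise comparisons, no overlap between the libraries of the groups. Provisional names were left out, and 1 gene that met the rule is not reported here. A fixed set of 25 genes of the Cdk7 complex, thermogenesis, adipocytes, lipid metabolism, macrophages and matrix was added, and up to 4 members of each list with the smallest adjusted p.

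The main gene test was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold, and the list test with 1 raised list. The alternatives, permutations and splits were not simulated. The simulated changes were few, with as many raised as lowered, and so cannot test the scaling between libraries. Of the 2-fold changes, 71 were recovered for CL in wt, 86 for CL in ko, 70 for ko against wt under saline, 80 for ko against wt under CL and 57 for the difference, with at most 8 unchanged genes called. Of the 1.5-fold changes, 59, 53, 54, 53 and 33 were recovered in the same order. A single Cdk7 value was also tested by exact two-sided permutation of libraries.

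The alternatives tried were DESeq2 1.42.0 with its Wald test, its size factors in edgeR, limma voom with quality weights, no filter on low counts, at least 1 CPM in at least 6 libraries, a robust fit, a block on the replicate number, only the 6 libraries compared, and leaving out each library in turn. Further alternatives were chosen after seeing the data: library size without a scaling factor, a motile cilia score as a covariate (log2 of the mean CPM plus 0.05), and leaving out 3 libraries together. The 3 libraries were wt saline 1 with ciliated duct genes, wt saline 2 with seminal vesicle genes and ko CL 2 with immunoglobulin genes. Another 4 lists for epithelia were also written after the data were seen. Because the model holds 1 mean per group, the slope of the motile cilia score comes only from spread within groups. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures. The floor for a gene without counts in a group was 3 counts over the group, which covers counting error only.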

Results

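RNA was sequenced from the perigonadal white fat of mice with intact Cdk7 (wt) and of mice with an adipose-specific Cdk7 knockout (ko). Cdk7 is a kinase of the general transcription factor TFIIH and also activates cell cycle kinases. Mice of both genotypes received saline or CL for 7 days, and each of the 4 groups had 3 libraries of 2 pooled mice. CL, which the labels give only by this abbreviation, was read as the beta-3-adrenergic agonist that drives lipolysis and brown-like remodelling of white fat. Libraries held 21892817 to 27985019 gene counts, and 16554 genes were tested. The first principal component (40.3% of the variance) set the ko CL libraries, at 70.7 to 89.3, apart from all others, at -45.2 to -10.9. The second (34.8%) set wt CL, at -68.8 to -62.5, apart from ko saline, at 50.2 to 62.1.

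Cdk7 itself was measured first, because it checks the labels. Cdk7 (ENSMUSG00000069089, GRCm38 chromosome 13, 100702631 to 100730939, minus strand) was at 29.6 ± 0.35 CPM in wt saline and 32.7 ± 2.6 in wt CL (SD, n = 3 each). It was at 11.4 ± 0.36 CPM in ko saline and 20.4 ± 2.9 in ko CL (SD, n = 3 each). All 6 ko libraries, at 11.02 to 23.56 CPM, lay below all 6 wt libraries, at 29.3 to 35.4 CPM (exact two-sided permutation test, p = 0.00216, the smallest that 6 against 6 can give). That test permuted all libraries freely and ignored treatment. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of ko against wt was -1.38 ± 0.10 under saline (SE, adjusted p = 6.21e-06) and -0.68 ± 0.09 under CL (adjusted p = 3.64e-05). With 3 against 3 libraries an exact permutation test cannot go below p = 0.1, which both comparisons reached. Within ko mice Cdk7 was higher under CL than under saline, by 0.84 ± 0.10 (adjusted p = 1.01e-05), and in wt mice it was not called different (0.14 ± 0.09, adjusted p = 0.251). The difference of these responses was 0.70 ± 0.13 (adjusted p = 0.000919). The titles therefore match the Cdk7 levels, while the genotype characteristic, which follows treatment, gave a log2 fold change of 0.36 for libraries tagged as knockout (adjusted p = 0.418). The 2 partners of Cdk7 in its kinase complex changed less: Ccnh, encoding cyclin H, differed by 0.25 ± 0.09 under saline (adjusted p = 0.0659) and 0.09 ± 0.09 under CL (adjusted p = 0.407). Mnat1, the assembly factor of the complex, differed by -0.07 ± 0.07 under saline (adjusted p = 0.575) and fell by 0.35 under CL (SE 0.07, adjusted p = 0.00127), a direction that turned to 0.04 with library size alone.

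**Figure D1:**
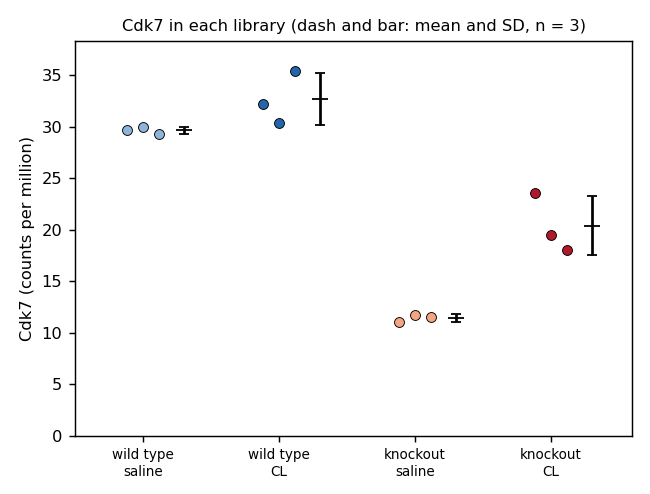
Cdk7 level in CPM (vertical axis) in each of the 12 libraries (points), by group (horizontal axis), with the mean and SD of 3 libraries beside each group. The 6 knockout libraries lie between 11.02 and 23.56 and the 6 wild-type libraries between 29.3 and 35.4.

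The response to CL in wt fat was a rise of thermogenic, mitochondrial and lipid-metabolic genes together with cell cycle genes. Ucp1, the uncoupling protein of brown and beige fat, rose from 0.196 ± 0.18 to 83.2 ± 9.9 CPM (SD, n = 3 each, log2 fold change 8.66 ± 0.74 SE, adjusted p = 4.46e-06). Elovl3, a fatty acid elongase of cold-exposed brown fat, rose from 0.457 ± 0.20 to 137 ± 3.2 CPM (8.19 ± 0.57, adjusted p = 1.09e-06). Gene values given below without a unit are log2 fold changes. The lipid droplet protein gene Cidea rose 10.48-fold, the cytochrome oxidase subunit genes Cox7a1 and Cox8b 11.7-fold and 9.91-fold, and Dio2, which makes active thyroid hormone, 5.54-fold. The other largest increases were in Wnt8b, Aadac, Slc25a34, Lipg and Ppp1r3b, at log2 fold changes of 3.38 to 4.18. Sfrp5, a secreted Wnt inhibitor of adipocytes, fell by 5.92 on the log2 scale (SE 0.44), Nnat fell from 533 ± 78 to 16.5 ± 5.3 CPM, and Acta1 (-5.05), Hspb7 (-3.89), Prr32 (-3.79), Plppr3 (-3.09), Folh1 (-3.08) and Timp4 (-2.68) were also among the largest decreases. Acsbg1 (adjusted p = 0.0273) and Prom1 (-2.66, adjusted p = 0.0418) were called lower too, but rested on wt saline library 1, at 15.7 and 22.3 CPM against at most 1.42 and 2.81 in the other 2 wt saline libraries, and without it they were at -0.89 and -0.72 and no longer called.

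Of 47 nuclear genes of oxidative phosphorylation, 46 rose under CL in wt, with a median log2 fold change of 1.06 (camera adjusted p = 4.81e-46, and adjusted p = 0.0903 with an estimated correlation). Uqcrfs1 of complex III rose 2.99-fold and Cox7b of complex IV 2.56-fold. All 19 genes of the tricarboxylic acid cycle rose (median 1.21, adjusted p = 6.85e-30, and adjusted p = 0.0903 with an estimated correlation), among them Idh3g (1.31) and Sdha (1.27). The 7 mitochondrially encoded messenger RNAs that could be tested all rose (median 1.35, adjusted p = 2.18e-16, and adjusted p = 0.0903 with an estimated correlation). mt-Nd1 and mt-Co1 were each at 1.49. Mitochondrial genes took 9.97 ± 0.43% of gene counts in wt CL against 4.76 ± 0.30% in wt saline (SD, n = 3 each). Of 24 genes of mitochondrial fatty acid oxidation, 21 rose and 1 fell (median 1.45, adjusted p = 3.01e-34, and adjusted p = 0.0825 with an estimated correlation). Acaa1b rose 5.51-fold, Pdk4, which restrains pyruvate oxidation, 4.88-fold, and Slc25a20, the carnitine carrier, 3.45-fold. The thermogenic list had 19 of 28 members higher and 2 lower (20 and 2 adjusted over the list alone, median 1.44, adjusted p = 1.1e-12, and adjusted p = 0.0903 with an estimated correlation). Acot11 was at 2.11 and Pank1 at 2.05. Ppargc1a, a coactivator of mitochondrial genes, rose by 0.71 ± 0.17, and Adrb3, the receptor of beta-3 agonists, fell by 0.51 ± 0.10. Mitochondrial chaperones and proteases had 18 of 21 members higher (19 adjusted over the list alone, median 0.38, adjusted p = 2.79e-09, and adjusted p = 0.0903 with an estimated correlation).

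Genes of lipid synthesis rose alongside those of oxidation in wt fat. Of 26 genes of fatty acid and triglyceride synthesis, 22 rose and 1 fell (median 1.30, adjusted p = 9.71e-15, and adjusted p = 0.113 with an estimated correlation). The citrate carrier gene Slc25a1 was at 2.22, the citrate-cleaving enzyme gene Acly at 2.14 and Acacb at 2.02. Fasn (0.96), Acaca (1.42) and the desaturase gene Scd1 (1.07) rose too, and Scd1 alone was at 98197 ± 5036 CPM in wt CL (SD, n = 3). Cholesterol synthesis had 20 of 23 members higher and 1 lower (21 and 1 adjusted over the list alone, median 1.20, adjusted p = 8.31e-22, and adjusted p = 0.0903 with an estimated correlation). Cyp51 was at 2.71 and Insig1 at 2.07. Glycolysis had 17 of 22 higher and 1 lower (median 0.71, adjusted p = 3.37e-10, and adjusted p = 0.113 with an estimated correlation), and PPAR targets 15 of 25 higher and 1 lower (15 and 2 adjusted over the list alone, median 0.87, adjusted p = 5.87e-12, and adjusted p = 0.0825 with an estimated correlation). Fabp5 was at 1.88. Lipolysis genes had 9 of 20 higher and 2 lower (median 0.33, adjusted p = 0.00697, and adjusted p = 0.501 with an estimated correlation). The droplet protein gene Plin5 was at 1.97, Abhd5 at 1.11 and the triglyceride lipase gene Pnpla2 at 0.51. The adipocyte identity list was not called (9 of 28 higher, 6 lower, 9 and 7 adjusted over the list alone, median 0.11, mean -0.04, adjusted p = 0.714), with Fabp4 at 0.53, Pparg at 0.17 (adjusted p = 0.264), Adipoq at -0.27 (adjusted p = 0.0773) while Lep fell by 1.004 (adjusted p = 1.73e-05). Of 35 proliferation genes, 31 rose and none fell (32 adjusted over the list alone, median 1.49, adjusted p = 2.58e-23, and adjusted p = 0.0903 with an estimated correlation). Tpx2 was at 2.37, Top2a at 2.09 and Rrm2 at 2.06.

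Markers of several non-adipocyte cell types fell in wt fat under CL. All 18 mesothelial markers fell (median -1.18, adjusted p = 1.48e-12, and adjusted p = 0.0903 with an estimated correlation). Msln was at -1.67 and Ezr at -1.21. Some of these markers, such as Krt8 and Cdh1, are also general epithelial genes. Of 24 macrophage markers, 21 fell (median -0.67, adjusted p = 4.33e-11, and adjusted p = 0.132 with an estimated correlation). Lyve1 was at -1.16, Ccr2 at -1.14, Mrc1 at -0.81 and Adgre1, the F4/80 antigen, at -0.65. Fibroblast and progenitor markers had 17 of 24 lower (18 adjusted over the list alone, median -0.60, adjusted p = 1.21e-09, and adjusted p = 0.113 with an estimated correlation). Dpt was at -1.44. Collagen and matrix genes had 23 of 36 lower and 1 higher (median -0.52, adjusted p = 3.84e-08, and adjusted p = 0.206 with an estimated correlation). Fn1 was at -1.17. MHC class II genes had 9 of 14 lower (median -0.75, adjusted p = 0.000311, and adjusted p = 0.178 with an estimated correlation). Endothelial markers were not called (7 of 24 higher, 3 lower, median 0.09, adjusted p = 0.714). In total 3249 genes were higher and 2836 lower under CL in wt, 709 and 723 of them at least 2-fold. With library size alone the counts were 1329 higher and 8048 lower, and the median of all genes was -0.33, against -0.0118 with TMM. The 10 most abundant genes held 24.0% of counts in wt CL and 16.2% in wt saline. Without wt saline 1, wt saline 2 and ko CL 2 the counts were 1707 and 1468, with 1 wt saline library left and the spread taken from the other groups.

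In ko fat, CL raised macrophage and lysosomal genes and cell cycle genes, and lowered adipocyte genes. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), rose from 20.5 ± 3.8 to 3160 ± 790 CPM (SD, n = 3 each, log2 fold change 7.27 ± 0.44 SE, adjusted p = 3.72e-08). The proton pump subunit gene Atp6v0d2 rose by 6.84 ± 0.42 (adjusted p = 3.95e-08), Spp1, encoding osteopontin, 53.5-fold, and Tm4sf19 79.8-fold. Myh15, Vsig8, Olfr111 and St18 rose by 5.58 to 6.71. Ucp1 rose here as well, to 37.7 ± 24 CPM (8.43 ± 0.82, adjusted p = 2.54e-06), with ko CL library 1 at 10.2 CPM and the other 2 at 51.0 and 51.9. Elovl3 rose by 6.48 ± 0.62, Cox8b by 2.25, Cidea by 1.61 and Dio2 by 1.14, and without ko CL library 2 Cidea was at 0.99 and no longer called. Adrb3 fell by 2.48 ± 0.10 (adjusted p = 3.25e-09), from 409 ± 33 to 73.0 ± 10 CPM (SD, n = 3 each).

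Sfrp5 fell by 5.23 ± 0.38 in ko fat. Among the other largest decreases were Ush1c, Ccdc153, Slc7a9, Mmp7, Prom2, ccdc198, Sall1 and Dcdc2a, at -5.16 to -4.34. With the motile cilia score as a covariate 6 of these 8 turned positive but were not called (adjusted p = 0.17 to 0.888). Ccdc153, 1 of the 6, is itself in the list behind that score, so its shift was partly built in. The matrix protease gene Mmp7 was at 29.1 to 40.5 CPM in ko saline, 12.5 in wt saline 1, at most 0.641 in the other 2 wt saline libraries and at most 2.81 in ko CL.

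Of 24 macrophage markers, 19 rose and 3 fell under CL in ko (median 1.91, adjusted p = 4.9e-19, and adjusted p = 0.298 with an estimated correlation). The protease gene Ctss was at 4.01, Cd68 at 3.83, Ms4a7 at 3.76 and Adgre1 at 3.42. Lipid-associated macrophage and lysosome genes had 19 of 22 higher and 2 lower (median 2.10, adjusted p = 4.27e-18, and adjusted p = 0.221 with an estimated correlation). The lipid receptor gene Trem2 was at 5.51 and Itgax at 4.37. Proliferation genes had 34 of 35 higher (median 1.75, adjusted p = 4.27e-18, and adjusted p = 0.302 with an estimated correlation). Tpx2 was at 2.35, Cenpa at 2.06 and Rrm2 at 2.01. MHC class II genes had 12 of 14 higher and 2 lower (median 1.18, adjusted p = 1.14e-05, and adjusted p = 0.302 with an estimated correlation). Ciita was at 1.96. Neutrophil, mast cell and eosinophil markers had 12 of 18 higher and 1 lower (14 and 1 adjusted over the list alone, median 1.24, adjusted p = 0.000929, and adjusted p = 0.298 with an estimated correlation). Csf3r was at 2.75 and Cpa3 at 1.41. B and plasma cell markers had 8 of 17 higher and 1 lower (median 0.57, adjusted p = 0.0203, and adjusted p = 0.827 with an estimated correlation). Cd22 was at 4.58 and Blnk at 3.55. That list rested on ko CL library 2, where Ighm was at 2575 CPM against 407 and 460 in the other 2, and without it the list median was -0.33 and the call was lost. Ribosomal protein genes had 35 of 37 higher (median 0.48, adjusted p = 1.87e-05, and adjusted p = 0.827 with an estimated correlation). Collagen and matrix genes had 18 of 36 higher and 6 lower (18 and 7 adjusted over the list alone, median 0.28, adjusted p = 0.0203, and adjusted p = 0.854 with an estimated correlation). Mmp2 was at 1.68, Col1a1 at 1.64 and Postn at 1.55. The list call was lost without ko saline 1 (median 0.15) or without ko CL 1 (median 0.22).

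Of 28 adipocyte identity genes, 19 fell and 1 rose in ko fat under CL (median -0.53, adjusted p = 4.34e-10, and adjusted p = 0.302 with an estimated correlation). Mest was at -2.71, Lep at -1.67, Rbp4 at -1.62, Adipoq at -1.40, Cebpa at -0.50, Fabp4 at -0.47 and Pparg, the master regulator of adipocytes, at -0.41. Lipolysis genes had 11 of 20 lower and 5 higher (median -0.46, adjusted p = 0.00696, and adjusted p = 0.827 with an estimated correlation). Pde3b was at -1.16, Aqp7 at -1.01, the hormone-sensitive lipase gene Lipe at -0.63, Plin1 at -0.50 and Pnpla2 at -0.42. Endothelial markers had 19 of 24 lower (1 higher and 19 lower adjusted over the list alone, median -0.50, adjusted p = 0.000229, and adjusted p = 0.708 with an estimated correlation). Cldn5 was at -1.15 and Gpihbp1 at -1.01. Smooth muscle markers had 10 of 17 lower and 1 higher (median -0.38, adjusted p = 0.0197, and adjusted p = 0.827 with an estimated correlation). Mcam was at -1.76. The list call was lost without ko CL 1 (median -0.33). Mesothelial markers had 10 of 18 lower and 1 higher (12 lower adjusted over the list alone, median -0.56, adjusted p = 0.0231, and adjusted p = 0.827 with an estimated correlation). Krt8 was at -2.17. The list call was lost without ko saline 3 (median -0.44), ko CL 2 (-0.56) or ko CL 3 (-0.52). This list also holds general epithelial genes, such as Krt8, Krt18 and Cdh1. Epcam, an epithelial gene outside it, was at 10.1 to 15.1 CPM in ko saline and 0.216 to 1.54 in ko CL. A fall of mesothelial RNA could therefore not be told apart from a fall of other epithelial RNA. The thermogenic list was not called (14 of 28 higher, 8 lower, 15 and 8 adjusted over the list alone, median 0.49, adjusted p = 0.64), nor was oxidative phosphorylation (9 of 47 higher, 2 lower, 5 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.755). Fasn (0.30, adjusted p = 0.281), Acaca (-0.06, adjusted p = 0.837) and Scd1 (0.18, adjusted p = 0.483) were not called. In total 4497 genes were higher and 4546 lower, 1657 and 1601 of them at least 2-fold, and with the motile cilia score as a covariate 2288 and 1744.

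**Figure D2:**
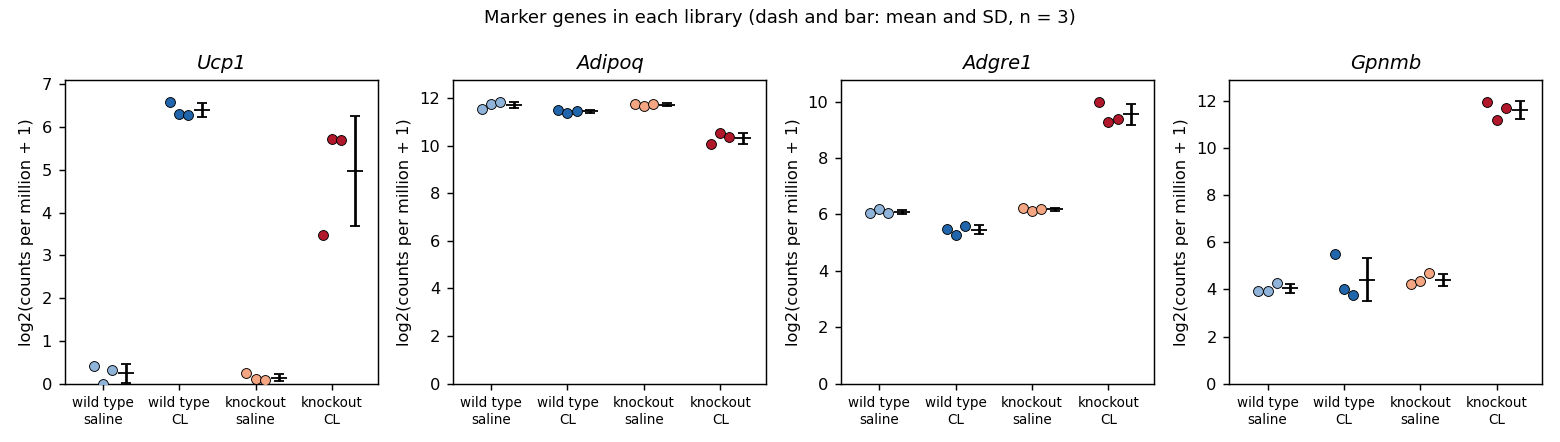
Levels of Ucp1, Adipoq, Adgre1 and Gpnmb as log2 of CPM plus 1 (vertical axes) in each library (points), by group (horizontal axes), with the mean and SD of 3 libraries. Gpnmb and Adgre1 are highest in the 3 knockout CL libraries, where Adipoq is lowest, and Ucp1 is high in both CL groups.

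The difference between the CL responses of the genotypes was tested directly, and it covered 7510 genes, 3607 with a more positive response in ko and 3903 with a more negative one. Macrophage markers responded more positively in ko for 21 of 24 genes and more negatively for 1 (21 and 2 adjusted over the list alone), with a median difference of 2.63 (adjusted p = 5.59e-34, and adjusted p = 0.0897 with an estimated correlation). Ctss differed by 4.59 ± 0.20 and Adgre1 by 4.07 ± 0.22 (adjusted p = 5.92e-08). Oxidative phosphorylation responded less in ko for 41 of 47 genes (1 higher and 43 lower adjusted over the list alone, median -0.92, adjusted p = 7.56e-15, and adjusted p = 0.252 with an estimated correlation). Sdha was at -1.27. All 19 tricarboxylic acid cycle genes (median -1.07, adjusted p = 6.27e-10, and adjusted p = 0.252 with an estimated correlation) and 20 of 23 cholesterol synthesis genes (median -1.56, adjusted p = 1.58e-13, and adjusted p = 0.169 with an estimated correlation) did so too, with Insig1 at -2.51. The thermogenic list had 15 of 28 lower and 1 higher (median -1.19, adjusted p = 0.000178, and adjusted p = 0.247 with an estimated correlation). Adrb3 was at -1.98, Cidea at -1.78, Dio2 at -1.33 and Ppargc1a at -1.27. For Ucp1 the difference was -0.23 ± 2.63 (adjusted p = 0.951) and was not called. Its saline levels were near 0, where this standard error is only approximate and wider than those of the 2 responses imply. The responses of Ucp1 could therefore not be compared. Elovl3 (-1.71 ± 1.32, adjusted p = 0.318) and Cox8b (-1.06 ± 0.58, adjusted p = 0.155) were not called. Adipocyte identity genes had 19 of 28 lower and 1 higher (21 lower and 1 higher adjusted over the list alone, median -0.77, adjusted p = 1.31e-07, and adjusted p = 0.228 with an estimated correlation). Adipoq was at -1.13 and Pparg at -0.58.

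Proliferation genes rose in both genotypes, and the difference was not called (11 of 35 higher, 1 lower, 11 and 0 adjusted over the list alone, median 0.18, adjusted p = 0.183). Across all genes, 937 were higher under CL in both genotypes (883 expected from independent lists) and 1197 lower in both (779 expected), while 717 rose in wt and fell in ko (892 expected) and 800 did the opposite (770 expected). The count higher in both was near the expected one and depended on single libraries, at 1029 without ko CL 1 (786 expected) and 693 without ko CL 3 (702 expected). Among genes changed at least 2-fold, 215 were higher in both (71.0 expected) and 350 lower in both (69.9 expected). Genes lower in both can include those high in wt saline 1 and in ko saline, as motile cilia genes were. Wt saline 1 was over 2-fold above both other wt saline libraries for 17.3% of genes at least 2-fold lower in wt. For genes at least 2-fold lower in ko this share was 30.5%, and for all genes tested 3.97%. The share among the 350 was not measured. The log2 fold changes had a Pearson correlation of 0.39 and a Spearman correlation of 0.15 across genes, which are not independent replicates. The 2 contrasts share no library. Genes called higher in wt had a median of 0.51 there and 0.03 in ko, and genes called lower in wt -0.66 and -0.16, where the choice by the wt result enlarges the wt medians. With library size alone, the counts of genes with a more positive and a more negative response were 5386 and 2267, and the median of all genes was 0.20, against -0.0277 with TMM.

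**Figure D3:**
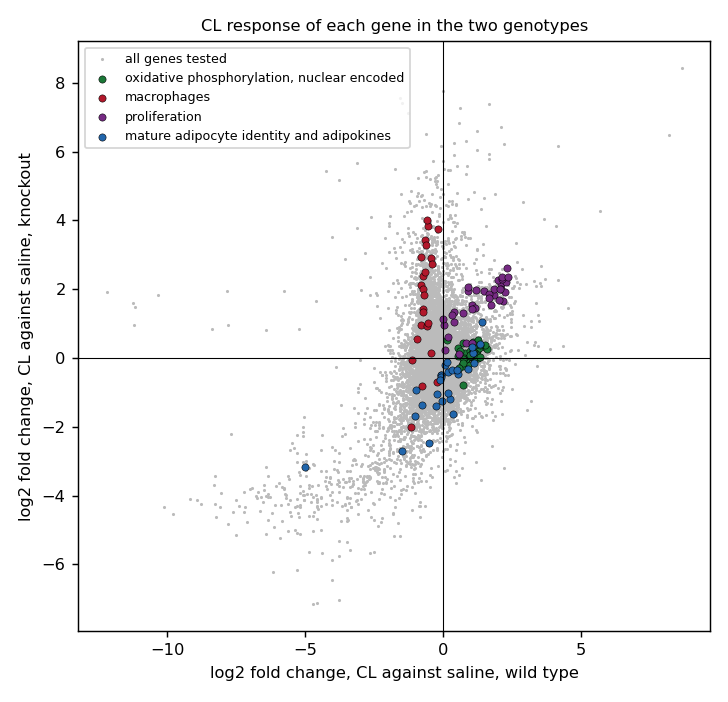
Log2 fold change of CL against saline in wild type (horizontal axis) and in knockout (vertical axis) for each of 16554 genes (grey), with members of 4 lists in colour. Oxidative phosphorylation genes lie right of 0 with a knockout median of 0.11, macrophage markers lie left of 0 with a knockout median of 1.91, and proliferation genes have medians of 1.49 and 1.75.

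In ko fat under saline, adipocyte and lipid-storage genes were lower and p53 target genes higher than in wt. Motile cilia genes separated the same groups, at 8.14 ± 1.18 CPM per gene in ko saline and 1.78 ± 1.85 in wt saline (SD, n = 3 each). Of 28 adipocyte identity genes, 14 were lower and 1 higher in ko than in wt (14 lower and 3 higher adjusted over the list alone, median -0.32, adjusted p = 3.24e-08, and adjusted p = 0.546 with an estimated correlation). The adipokine gene Retn was at -1.49 ± 0.16, Plin1 at -0.90, Adrb3 at -0.86 ± 0.10, Fabp4 at -0.71 and Cebpa at -0.42. Adipoq (0.02, adjusted p = 0.946), Lep (-0.06, adjusted p = 0.754) and Pparg (-0.16, adjusted p = 0.387) were not called. Lipolysis and droplet genes had 10 of 20 lower and 1 higher (13 lower and 1 higher adjusted over the list alone, median -0.39, adjusted p = 3.99e-08, and adjusted p = 0.509 with an estimated correlation). Cidec was at -1.03, Lipe at -0.93 and Plin4 at -0.83. Fatty acid and triglyceride synthesis had 13 of 26 lower and 2 higher (14 lower and 3 higher adjusted over the list alone, median -0.53, adjusted p = 5.35e-07, and adjusted p = 0.684 with an estimated correlation). Acss2 was at -1.64, Scd1 at -1.52, Fasn at -1.27, Pck1 at -0.99 and Dgat2 at -0.95. Of 22 p53 target and senescence genes, 7 were higher and none lower (8 adjusted over the list alone, median 0.25, adjusted p = 3.24e-08, and adjusted p = 0.0517 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, was 2.83-fold higher (adjusted p = 2.74e-06). On the log2 scale Eda2r was at 1.86 ± 0.23, Ccng1 at 0.55 and Mdm2, the ubiquitin ligase of p53, at 0.48. Proliferation genes had 2 of 35 higher and 1 lower (1 higher and none lower adjusted over the list alone, median 0.25, adjusted p = 0.0186, and adjusted p = 0.971 with an estimated correlation), a list call lost with library size alone, without wt saline 1 and without ko saline 3. With the motile cilia score as a covariate, all 17 genes named as changed in this paragraph kept their direction, but only Cdkn1a (adjusted p = 0.00555), Plin4 (0.0323), Pck1 (0.0328) and Retn (0.035) kept their call. Among the others, Plin1 was then at -0.98 (adjusted p = 0.255), Scd1 at -1.16 (adjusted p = 0.273) and Eda2r at 1.48 (adjusted p = 0.215). Lipe (-0.92), Dgat2 (-0.96), Cidec (-0.94), Cebpa (-0.39) and Ccng1 (0.64) stayed near or beyond their values without the score. Adrb3 (-0.74), Fabp4 (-0.55), Acss2 (-1.31), Fasn (-1.02) and Mdm2 (0.39) came nearer to 0. The standard errors of all these genes were larger with the score. Its slope leaned on wt saline 1, because motile cilia genes were at 0.613 to 3.92 CPM per gene within wt saline. Within the other groups they were at 6.90 to 9.26 (ko saline), 0.649 to 0.711 (wt CL) and 0.924 to 1.63 (ko CL). Values with the score are therefore extrapolated over the gap between the groups.

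The long nuclear RNA Neat1 was lower in ko by 1.38 on the log2 scale (log2 fold change -1.38 ± 0.10, adjusted p = 6.21e-06). It belongs to a list of structural and nuclear-retained RNAs with 5 of 7 members lower (6 adjusted over the list alone, median -0.47, adjusted p = 4.51e-08, and adjusted p = 0.0126 with an estimated correlation), and this was the only list call in any comparison that held with an estimated correlation. Among single genes, the largest decreases were in Cyp2f2 (-4.38 ± 0.59), the interferon-inducible gene Ifi27l2a (-2.94 ± 0.16, adjusted p = 2.13e-06), Alb (-2.83), Acsm3 (-2.80), Clstn3 (-2.29), Golga7b (-2.25), Pon1 (-2.16), Apoc1 (-1.999), Cldn22 (-1.98) and Acta1 (-1.83). Of these 10, Clstn3 is also in the thermogenic list, Apoc1 in that of lipid-associated macrophages and Acta1 in that of skeletal muscle. With the motile cilia score as a covariate all 10 stayed lower, but 6 lost their call: Cyp2f2 (adjusted p = 0.136), Golga7b (0.234), Pon1 (0.0853), Apoc1 (0.194), Cldn22 (0.171) and Acta1 (0.753). Of these 6, Pon1 was then at -2.52 ± 0.58, Cldn22 at -2.05 ± 0.56 and Apoc1 at -1.96 ± 0.56, near or beyond their values without the score but with larger standard errors, while Cyp2f2 was at -3.34, Golga7b at -1.63 and Acta1 at -0.59. Alb was at 125 CPM in wt saline 1, at 19.2 and 47.9 in the other 2 wt saline libraries and at 7.94 to 10.3 in ko saline. Endothelial markers had 3 of 24 lower (median -0.17, adjusted p = 0.0383, and adjusted p = 0.971 with an estimated correlation), and with library size alone their median was -0.0167 and the call was lost. Fibroblast markers had 3 of 24 lower and 1 higher (median -0.14, adjusted p = 0.0316, and adjusted p = 0.971 with an estimated correlation), and with library size alone their median was 0.01 and the call was lost. Ribosomal protein genes had 1 of 37 lower (none adjusted over the list alone, median -0.13, adjusted p = 0.00198, and adjusted p = 0.971 with an estimated correlation), and with library size alone their median was 0.03. Macrophage markers had none of 24 called (median -0.10, adjusted p = 0.663), oxidative phosphorylation 1 of 47 higher (median -0.06, adjusted p = 0.585) and the thermogenic list 2 of 28 higher and 4 lower (3 and 5 adjusted over the list alone, median -0.13, adjusted p = 0.486).

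The largest increases in ko saline, which include the epithelial adhesion gene Epcam, were in Sectm1b, ccdc198, Rgs22, Ak7, Dsg2, Greb1, Epcam, Dao, Slc9a3 and Bbox1, at adjusted p = 0.0137 to 0.0489. With the motile cilia score as a covariate none was called and 9 turned negative. Dnah5, a dynein of motile cilia named after its values were seen, was at 15.2 to 17.3 CPM in ko saline, 6.89 in wt saline 1, and at most 0.356 in wt saline 2 and 3. In total 1323 genes were higher and 1068 lower, 579 and 175 of them at least 2-fold. With the motile cilia score as a covariate 28 and 71 were called. For the 2391 genes called without it, the median absolute log2 fold change went from 0.551 to 0.421 and the median standard error from 0.116 to 0.211. The score had a mean of 0.397 in wt saline and 3.02 in ko saline. Without wt saline 1, wt saline 2 and ko CL 2 they were 811 and 458, with 1 wt saline library left and the spread taken from the other groups. With library size alone the counts were 3733 and 506, with a median of all genes of 0.15 against -0.00742 with TMM, and with limma voom 2236 and 1804. Leaving out single libraries gave 509 (without wt saline 3) to 1402 (without wt saline 1) genes higher and 551 (without ko saline 2) to 867 (without wt saline 1) lower. Both counts moved by over 1.5-fold without wt saline 2 (607 and 647), wt saline 3 (509 and 556), ko saline 1 (712 and 616) or ko saline 2 (562 and 551). Each of these 10 genes lost its call without wt saline 3 and without ko saline 2.

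**Figure D4:**
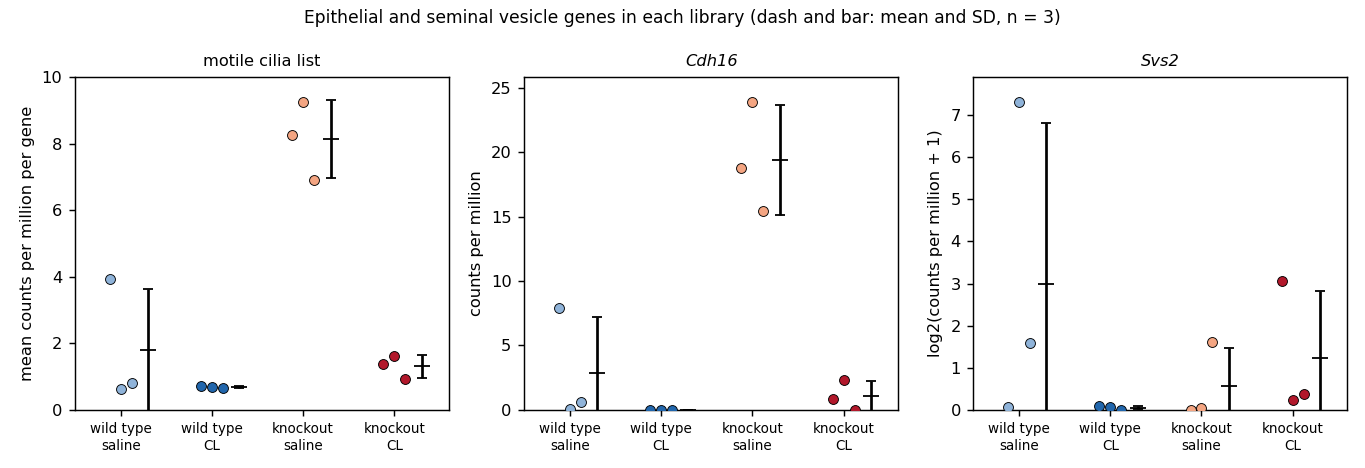
Mean level per gene of 28 motile cilia genes and level of Cdh16 in CPM, and level of Svs2 as log2 of CPM plus 1 (vertical axes), in each library (points), by group (horizontal axes), with the mean and SD of 3 libraries. Motile cilia genes and Cdh16 are high in the 3 knockout saline libraries and wild-type saline library 1, and Svs2 in wild-type saline library 2.

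Under CL the genotypes differed most: 4561 genes were higher and 4847 lower in ko than in wt, 2008 and 1378 of them at least 2-fold. Gpnmb was at 3160 ± 790 CPM in ko CL against 23.8 ± 17 in wt CL (SD, n = 3 each, log2 fold change 7.06 ± 0.44 SE, adjusted p = 3.34e-08), and Vsig8 (7.42), Atp6v0d2 (7.05), Tm4sf19 (6.95), Rnf128 (6.89), Spp1 (6.87), Myh15 (6.84), F7 (6.49) and Il1rn (6.47), which encodes an interleukin-1 antagonist, were also among the 10 largest. Hmga2, a chromatin protein gene of growing cells, was at 10.8 ± 4.5 CPM in ko CL and had 0 counts in wt CL, which at a floor of 3 counts over the group makes it at least 201-fold higher. The largest decreases were in Acsm3 (-4.45 ± 0.21), Adam2 (-3.93), Golga7b (-3.87), Acss2 (-3.62), Eci3 (-3.50), Lrtm1 (-3.22), Cldn22 (-3.21), Rgs7 (-3.13), Chrna2 (-3.13) and Cidea (-3.13). Adrb3 was lower by 2.83 on the log2 scale (-2.83 ± 0.10, adjusted p = 7.75e-10), at 73.0 ± 10 CPM against 521 ± 17 (SD, n = 3 each).

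Adipocyte identity genes were lower in ko CL for 25 of 28 members and higher for none (median -1.09, adjusted p = 1e-13, and adjusted p = 0.0955 with an estimated correlation). Rbp4 was at -2.25, Fabp4 at -1.70, Plin1 at -1.33, Adipoq at -1.11, Cebpa at -0.85, Pparg at -0.74 and Lep at -0.73. Fatty acid and triglyceride synthesis had 23 of 26 lower (24 adjusted over the list alone, median -1.88, adjusted p = 2.09e-11, and adjusted p = 0.151 with an estimated correlation). Pck1 was at -2.65, Scd1 at -2.41, Fasn at -1.93 and Acaca at -1.71. Lipolysis genes had 17 of 20 lower and 2 higher (median -1.32, adjusted p = 5.53e-11, and adjusted p = 0.0955 with an estimated correlation). Ces1d was at -2.32, Lipe at -1.46 and Pnpla2 at -1.27. Cholesterol synthesis had 21 of 23 lower and 1 higher (median -1.58, adjusted p = 7.56e-14, and adjusted p = 0.0955 with an estimated correlation). Insig1 was at -3.02. Oxidative phosphorylation had 46 of 47 lower (median -0.98, adjusted p = 9.77e-17, and adjusted p = 0.218 with an estimated correlation), fatty acid oxidation 22 of 24 lower and 2 higher (median -1.22, adjusted p = 1.83e-13, and adjusted p = 0.0955 with an estimated correlation). Pdk4 was at -2.43. PPAR targets had 20 of 25 lower and 2 higher (median -1.26, adjusted p = 1.06e-09, and adjusted p = 0.0925 with an estimated correlation). All 19 tricarboxylic acid cycle genes (median -1.14, adjusted p = 6.18e-11, and adjusted p = 0.218 with an estimated correlation) and all 7 mitochondrially encoded messenger RNAs (median -1.72, adjusted p = 5.35e-10, and adjusted p = 0.0955 with an estimated correlation) were lower. The thermogenic list had 20 of 28 lower and 1 higher (median -1.27, adjusted p = 2.21e-05, and adjusted p = 0.16 with an estimated correlation). Cox8b was at -2.58, Elovl3 at -2.22, Ppara at -2.12, Dio2 at -1.69 and Ppargc1a at -1.42. Ucp1 was at -1.15 ± 0.40 (adjusted p = 0.0267), a call lost without wt CL 1 and without wt CL 2. Its size rested on ko CL 1, and without that library it was at -0.697.

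Of 24 macrophage markers, 21 were higher and 2 lower in ko CL (median 2.40, adjusted p = 5.11e-29, and adjusted p = 0.0925 with an estimated correlation). Ctss was at 4.82 ± 0.16, Adgre1 at 4.16, Ms4a7 at 4.08 and Lyz2 at 3.71. Lipid-associated macrophage genes had 16 of 22 higher and 4 lower (median 2.67, adjusted p = 1.53e-12, and adjusted p = 0.0947 with an estimated correlation). Trem2 was at 5.62 and Itgax at 4.85. MHC class II genes had 12 of 14 higher and 1 lower (median 1.83, adjusted p = 5.69e-09, and adjusted p = 0.0947 with an estimated correlation), neutrophil, mast cell and eosinophil markers 14 of 18 higher and 1 lower (15 and 1 adjusted over the list alone, median 1.59, adjusted p = 0.000396, and adjusted p = 0.0955 with an estimated correlation) and cytokine and chemokine genes 18 of 31 higher and 3 lower (median 0.97, adjusted p = 0.000784, and adjusted p = 0.124 with an estimated correlation). Cxcl16 was at 2.68. Collagen and matrix genes had 22 of 36 higher and 2 lower (median 0.85, adjusted p = 6.14e-07, and adjusted p = 0.227 with an estimated correlation). Col1a1 was at 2.16 and Mmp2 at 1.90. Fibroblast markers had 19 of 24 higher and 2 lower (median 0.81, adjusted p = 7.75e-05, and adjusted p = 0.242 with an estimated correlation). Lum was at 1.74 and Pdgfra at 1.44. Endothelial markers moved the other way, with 20 of 24 lower and 1 higher (2 higher adjusted over the list alone, median -0.92, adjusted p = 2.49e-06, and adjusted p = 0.195 with an estimated correlation). Cldn5 was at -1.87 and Gpihbp1 at -1.56. Smooth muscle markers had 8 of 17 lower and 1 higher (median -0.35, adjusted p = 0.0253, and adjusted p = 0.495 with an estimated correlation), a median that turned to 0.03 with library size alone and a call lost without ko CL 1 (median -0.26). Proliferation genes had 22 of 35 higher (median 0.54, adjusted p = 0.00549, and adjusted p = 0.562 with an estimated correlation). With library size alone 8667 genes were higher and 2237 lower, and the median of all genes was 0.39, against 0.00298 with TMM.

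**Figure D5:**
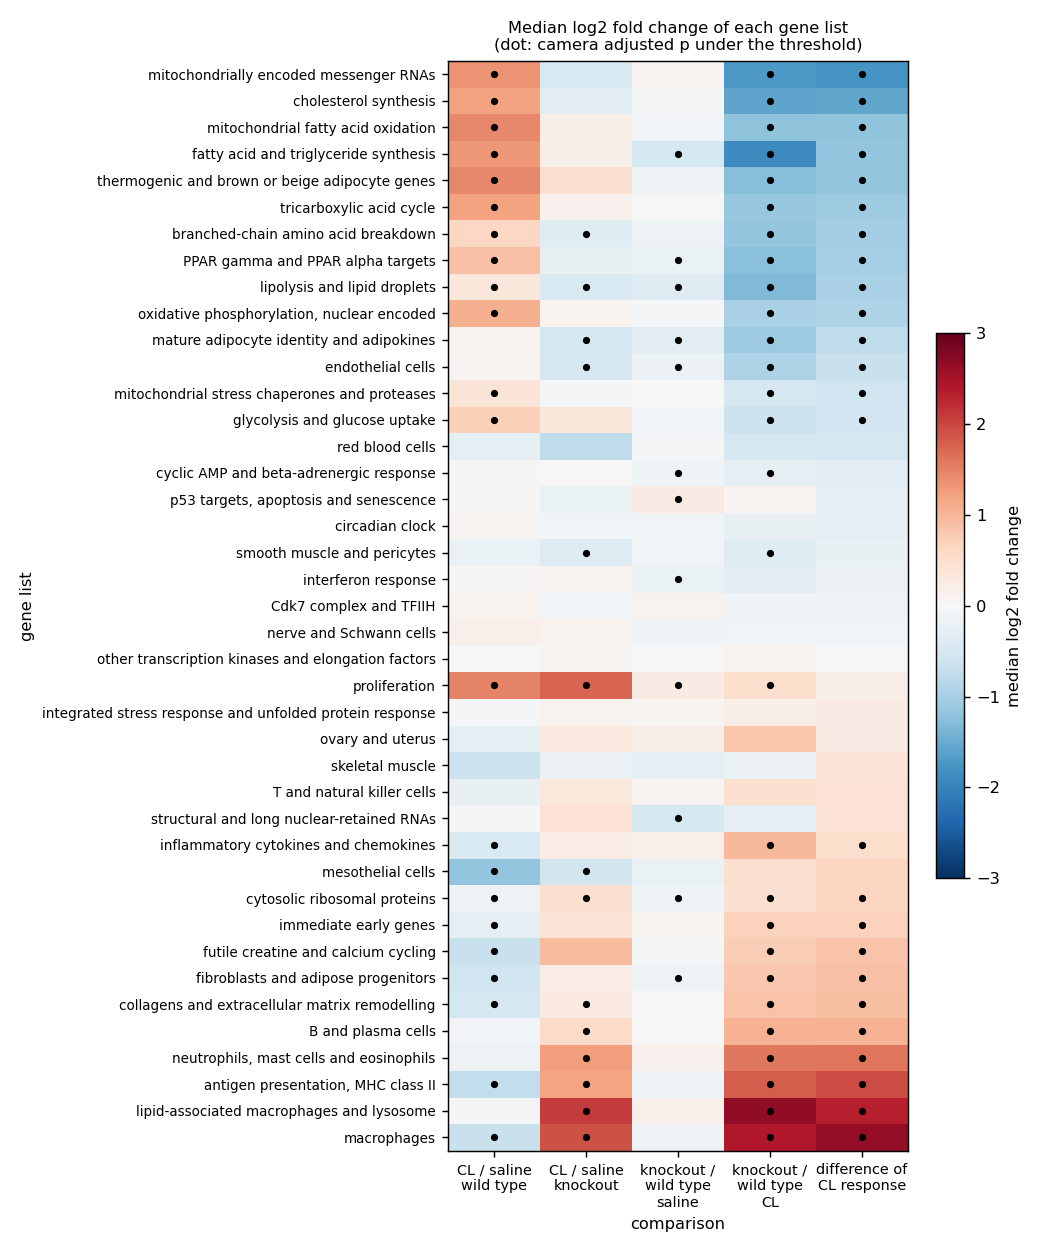
Median log2 fold change (colour, blue below 0 and red above) of 41 gene lists (rows) in the 5 comparisons (columns), with a dot where the camera adjusted p passed the threshold. The macrophage list has medians of 1.91 under CL in knockout and 2.40 in knockout against wild type under CL, and oxidative phosphorylation a median of 1.06 under CL in wild type.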

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

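The tests of other explanations below, apart from the splits of the libraries, were chosen after the results were seen. A direct test of the difference between the CL responses of ko and wt marked 3607 genes as more positive in ko and 3903 as more negative. The same test marked 25 gene lists, given here by the median difference on the log2 scale. More positive in ko were macrophages (2.63), lipid-associated macrophages and lysosome (2.34), MHC class II (1.97), neutrophils, mast cells and eosinophils (1.59), and B and plasma cells (1.04). Collagens and matrix (0.91), fibroblasts (0.88), futile creatine and calcium cycling (0.85), immediate early genes (0.69), ribosomal proteins (0.64) and cytokines (0.53) were more positive as well. More negative were mitochondrially encoded messenger RNAs (-1.78), cholesterol synthesis (-1.56), fatty acid oxidation (-1.20), fatty acid and triglyceride synthesis (-1.19), thermogenic genes (-1.19), the tricarboxylic acid cycle (-1.07), branched-chain amino acid breakdown (-1.03) and PPAR targets (-1.03). Lipolysis (-0.98), oxidative phosphorylation (-0.92), adipocyte identity (-0.77), endothelial cells (-0.68), mitochondrial chaperones (-0.59) and glycolysis (-0.58) were also more negative. The B and plasma cell value leaned on ko CL 2, where Ighm was highest, and without it the median was 0.30, still past the threshold. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.0897.

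Among single genes, the fitted difference was largest in Svs1 (14.11), Pate4 (12.85), Svs4 (12.65), Svs2 (12.19) and Svs5 (9.79), which rested on 1 library. In wt saline 2 they were at 68.5, 35.8, 155, 159 and 174 CPM, against at most 2.42 in the other 2 wt saline libraries, and without it none was called. Npas4 (7.25), Vsig8 (7.11), Gpnmb (6.67) and Atp6v0d2 (6.27) were also among the most positive. Hmga2 had a fitted value of 9.67, which is not a measured size because it had 0 counts in wt CL. Chrna2 (-4.23), Aadac (-3.6003), Adam2 (-3.36), Vil1 (-3.26), Fbp2 (-3.25), Elovl7 (-3.07), Esrrg (-2.85), Slc38a3 (-2.76), Tmem56 (-2.72) and Pdk4 (-2.64) were the most negative. Of the genes fixed beforehand, Adgre1 (4.07), Col1a1 (2.22) and Cdk7 (0.70) were more positive in ko. Adrb3 (-1.98), Cidea (-1.78), Acaca (-1.48), Dio2 (-1.33), Ppargc1a (-1.27), Adipoq (-1.13), Fabp4 (-0.998), Pnpla2 (-0.93), Scd1 (-0.89), Lep (-0.67), Pparg (-0.58), Cebpa (-0.44) and Mnat1 (-0.28) were more negative. List members were Ctss (4.59), Egr2 (4.37), Gatm (3.11), Mmp2 (1.79), Rpl3 (0.64), Sdha (-1.27), Gpihbp1 (-1.47) and Insig1 (-2.51). Reads that the comparisons did not use also differed from wt saline. Reads with more than 1 match made up 12.5% in wt CL and 8.86% in ko saline against 7.99% in wt saline, reads outside genes 2.31% in ko saline against 2.08%, and reads in overlapping genes 2.82% in ko CL against 2.61%. In wt CL these last 2 shares were lower than in wt saline, at 1.85% and 2.18%.

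Each comparison of 2 groups was repeated on all 10 splits of its 6 libraries into 3 and 3, which are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, reached the real count. Every other split mixes libraries of both groups, so the difference between the groups enters the spread and few calls could be foreseen. Any steady difference between the groups, such as that in motile cilia genes under saline, would give the same result. The real and highest other counts of changed genes were 6085 and 0 for CL in wt, 9043 and 1 for CL in ko, 2391 and 0 for ko against wt under saline, and 9408 and 0 for ko against wt under CL. For the difference, genotype was permuted within treatment. Of 100 permutations drawn from 200 possible, 2, including the real one, reached 7510 genes, a share of 0.02. The highest other, 8371, exchanged the genotypes within 1 treatment, which turns the difference into another contrast between the same 4 groups. Another 6 permutations that mixed genotypes under saline but kept the CL groups whole reached 6138 to 6698 genes, so that much of the count can come from the genotype contrast under CL alone.

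Adipocyte genes were lower and macrophage genes higher in ko CL than in wt CL. A lower share of adipocyte RNA alone would raise every other cell type, but the endothelial list had a median of -0.92, with 20 of 24 genes lower. This speaks only against a loss of adipocyte RNA with all other cell types unchanged. More macrophage RNA can lower adipocyte and endothelial shares together, so a wider change of cell makeup was not excluded. The scaling factor would have to carry the direction, but with library size alone the adipocyte median was -0.71 and the macrophage median 2.79. An effect of genotype inside adipocytes was not tested, because adipocytes were not separated from other cells.

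Genes at least 2-fold higher in ko than wt under saline, 579 in all, were weighed against RNA from a ciliated duct beside the fat. Of these, 83.6% were highest in wt saline 1 among the 3 wt saline libraries, against 35.4% of all genes tested, as such RNA would give. Wt saline 1 was picked because it carries motile cilia genes. Such genes were not taken out of the 579, so the share partly restates that choice. Kidney RNA did not account for them, since kidney genes were at 0.143 CPM per gene in ko saline, against 8.14 for motile cilia genes. Loss of Cdk7 remained open: 0 of 3 ko CL libraries were above wt saline 1 in motile cilia genes, with the highest at 1.63 CPM against 3.92.

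Cdk7 was higher in ko CL than in ko saline. The scaling factor did not carry this, since with library size alone the log2 fold change was 0.75. More RNA from cells that keep Cdk7 remained open: the difference of the CL responses was 0.70 ± 0.13 and Adipoq fell by 1.40 in ko, but cell makeup and treatment moved together.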

How the results depend on the processing

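Of the 101 list calls, 1 held with an estimated correlation, 93 with fry and 95 with library size alone, and 101 with DESeq2 size factors. Camera sets a list against the other genes, so scaling that shifts all genes alike can hardly change its calls. The 95 and 101 therefore say little about scaling. Medians of some called lists changed sign with library size alone. Among these were, for ko against wt, ribosomal proteins (0.03) and fibroblasts (0.01) under saline and smooth muscle (0.03) under CL. The number of lists called was 0 with an estimated correlation for CL in wt, CL in ko, ko against wt under CL and the difference, and 1 for ko against wt under saline. With fry it was 25 for CL in ko and 7 for ko against wt under saline. Of 360 results for named genes, 358 kept direction and side of the threshold with DESeq2 size factors (of 358 measured), 355 of 358 without a filter, 338 of 358 with limma voom, 336 of 358 with the robust fit and 334 of 347 with DESeq2. With 1 library left out 2283 of 2460 values did. Fewer results did with library size alone (328 of 358), without 3 doubted libraries (323) and with the motile cilia score (274, with 61 weaker and 22 reversed). Of 323 called results, 85 lost the call in at least 1 alternative. A block on the replicate number kept 347 of 358, but the labels do not say what the number stands for. Of 18 same-numbered pairs, 2 had a correlation above 0.1, which gives no sign of pairing but cannot exclude it.

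With library size alone the counts of genes higher and lower were 1329 and 8048 for CL in wt, 3733 and 506 for ko against wt under saline, and 8667 and 2237 for ko against wt under CL, with 2267 lower for the difference. This follows from the scaling, which was omitted. Directions that turned were, for CL in wt, Cdk7 (-0.18), Mnat1 (-0.22) and Pparg (-0.15). For ko against wt under saline they were Mnat1 (0.0852), Ppargc1a (0.00265), Lep (0.10) and Col1a1 (0.10), for ko against wt under CL Mnat1 (0.0357), and for the difference Ccnh (0.0640) and Ucp1 (0.00538).

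With the motile cilia score as a covariate, 2288 and 1744 genes were called for CL in ko and 28 and 71 for ko against wt under saline. In the latter, 2221 of 2391 calls kept their sign. The median absolute log2 fold change went from 0.551 to 0.421 and the median standard error from 0.116 to 0.211. The slope of the score came from spread within groups and leaned on wt saline 1, so values with the score are extrapolated between groups. For CL in ko, Ush1c (1.72), Ccdc153 (1.67), Slc7a9 (0.87), Mmp7 (1.31), ccdc198 (0.21), Dcdc2a (1.95), Scd1 (-0.17) and Fgf21 (-0.48) reversed. These reversed values were not called (adjusted p = 0.17 to 0.888), and Ccdc153 is itself in the list behind the score. For ko against wt under saline, Sectm1b (-0.81), ccdc198 (-0.16), Rgs22 (-1.25), Ak7 (-0.87), Dsg2 (-0.92), Greb1 (-0.45), Dao (-0.80), Slc9a3 (-0.72), Bbox1 (-0.54), Elovl3 (3.12), Lep (0.18), Acaca (0.0253) and Col1a1 (0.11) did, and for the difference Svs4 (-0.47). The cause was not tested.

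Without wt saline 1, wt saline 2 and ko CL 2, 1707 and 1468 genes were called for CL in wt and 811 and 458 for ko against wt under saline. Both then rest on 1 wt saline library, with the spread taken from the other groups, and fewer samples can give fewer calls. Leaving these out also removed wt saline 1, at 3.92 CPM per gene in motile cilia genes. The 3 ko saline libraries, at 6.90 to 9.26, were kept, so this alternative does not remove the motile cilia difference between the groups. Plin1 for CL in wt (0.0197) and, for ko against wt under saline, Adipoq (-0.10) and Col1a1 (0.0240) reversed. With limma voom the counts for ko against wt under saline were 2236 and 1804, and Acaca for CL in ko (0.28) and Adipoq for ko against wt under saline (-0.0253) reversed. The cause was not tested.

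Leaving out single libraries moved the counts past 1.5-fold only for ko against wt under saline. There they were 509 to 1402 higher and 551 to 867 lower, with 607 and 647 without wt saline 2, 509 and 556 without wt saline 3, 712 and 616 without ko saline 1, and 562 and 551 without ko saline 2. Cdk7 stayed at -1.39 to -1.34 under saline and -0.80 to -0.61 under CL. Some genes near 0 changed direction, with a lowest and highest value for CL in wt of -0.16 and 0.0216 (Plin1, 0.0216 without wt CL 3). For CL in ko they were -0.27 and 0.12 (Acaca, 0.12 without ko saline 1 and without ko CL 1), -0.0207 and 0.37 (Scd1, -0.0207 without ko saline 2) and -0.00252 and 0.85 (Fgf21, -0.00252 without ko CL 3). For ko against wt under saline they were -0.0491 and 0.0762 (Adipoq, -0.0491 without wt saline 1), -0.13 and 0.0369 (Lep, 0.0369 without wt saline 3) and -0.28 and 0.14 (Col1a1, 0.00178 without wt saline 2 and 0.14 without ko saline 1). Fgf21 for ko against wt under CL went from -0.32 to 0.32 (-0.0834 without wt CL 3, -0.32 without ko CL 3). Ucp1 for the difference went from -0.84 to 0.33 (0.30 without wt saline 2, 0.33 without ko saline 1, 0.21 without ko CL 1). The cause was not tested.

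With at least a 2-fold change required, 215 genes were higher under CL in both genotypes and 350 lower in both, against 71.0 and 69.9 expected. Fewer genes enter then. Without this requirement 937 and 1197 stood against 883 and 779 expected, and why the excess differed was not tested. With the genotype characteristic as genotype, ko against wt could not be compared within a treatment, because that tag follows treatment. The 6 libraries tagged knockout against the 6 tagged wild type, which is a comparison of treatments, gave 0.36 for Cdk7. Genes without about 10 counts in at least 3 libraries were not tested, and saline levels near 0, as for Ucp1, leave wide and only approximate standard errors.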

Other observations

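Several gene lists beyond those of the report moved. Branched-chain amino acid breakdown had 20 of 23 genes higher and 1 lower under CL in wt (21 and 1 adjusted over the list alone, median 0.63, adjusted p = 3.17e-13, and adjusted p = 0.113 with an estimated correlation). In ko it had 15 of 23 lower and 1 higher (median -0.36, adjusted p = 0.0203, and adjusted p = 0.854 with an estimated correlation). Immediate early genes had 7 of 21 lower under CL in wt (median -0.29, adjusted p = 0.00336, and adjusted p = 0.386 with an estimated correlation), a call lost with library size alone. In ko CL against wt CL 14 of 21 were higher (median 0.70, adjusted p = 0.000244, and adjusted p = 0.242 with an estimated correlation). Atf3 was at 5.27, Egr2 at 4.62 and Fos at 3.27 there. Creatine and calcium cycling genes had 5 of 9 lower and 1 higher under CL in wt (6 lower and 1 higher adjusted over the list alone, median -0.66, adjusted p = 0.0105, and adjusted p = 0.0903 with an estimated correlation). Under CL in ko they were not called (5 of 9 higher, 2 lower, median 0.94, adjusted p = 0.0546). They had 6 of 9 higher in ko CL than wt CL (median 0.73, adjusted p = 0.000491, and adjusted p = 0.0925 with an estimated correlation). Gatm, an enzyme of creatine synthesis, was at 3.14 and Ckb at 2.74. The cyclic AMP and beta-adrenergic response list was not called for CL in wt (median 0.05), CL in ko (-0.0045) or the difference (-0.31). It was called for ko against wt under saline (median -0.13) and under CL (-0.28). With library size alone these 2 medians turned to 0.02 and 0.10, and neither call held with an estimated correlation. Ribosomal protein genes had 34 of 37 higher in ko CL than wt CL (median 0.46, adjusted p = 1.91e-05, and adjusted p = 0.475 with an estimated correlation), with Rpl3 at 0.60. Interferon response genes had 4 of 27 lower in ko saline than wt saline (7 adjusted over the list alone, median -0.19, adjusted p = 0.00187, and adjusted p = 0.739 with an estimated correlation), with Ifit3 at -0.54, which was at -0.49 and not called with the motile cilia score (adjusted p = 0.397).

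Polr2a, the largest subunit of RNA polymerase II and a substrate of Cdk7, was higher in ko by 1.04 ± 0.09 under saline (adjusted p = 2.45e-05) and by 0.79 ± 0.09 under CL. The list of other transcription kinases and elongation factors was not called under saline (3 of 21 higher, 1 lower, median 0.0031, adjusted p = 0.464) or under CL (6 of 21 higher, 2 lower, 6 and 1 adjusted over the list alone, median 0.09, adjusted p = 0.418), where Cdk9 was at 0.75. The list of the Cdk7 complex and TFIIH was not called under saline (4 of 10 higher, 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.923) or under CL (2 of 10 higher, 4 lower, 2 and 5 adjusted over the list alone, adjusted p = 0.293). Under saline Gtf2h3 was at 0.31 and Gtf2h1 at 0.28, and with the motile cilia score both lost their call at 0.30 (adjusted p = 0.468) and 0.29 (adjusted p = 0.411). Circadian clock genes were not called for ko against wt under saline (0 of 18 higher, 2 lower, adjusted p = 0.57) or under CL (1 of 18 higher, 8 lower, median -0.22, adjusted p = 0.142). The integrated stress response was not called under saline (4 of 28 higher, 3 lower, 4 and 4 adjusted over the list alone, adjusted p = 0.802) or under CL (14 of 28 higher, 8 lower, adjusted p = 0.293).

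The epithelial lists were written after the data were seen. Motile cilia genes were at 8.14 ± 1.18 CPM per gene in ko saline, 1.78 ± 1.85 in wt saline, 0.677 ± 0.031 in wt CL and 1.31 ± 0.35 in ko CL (SD, n = 3 each). Absorptive duct genes were at 32.4, 26.7, 18.9 and 11.6 CPM per gene in the same order, mostly from Aqp1, at 311 to 395 CPM in ko saline and 417 to 431 in wt saline, and kidney genes at 0.143, 0.0714, 0.0395 and 0.0509. Seminal vesicle and prostate genes were at 66.1 CPM per gene in wt saline 2 and at most 3.54 in every other library. The epididymis and testis list had 2 of 25 genes past the filter and no test. Xist was at most 0.380 CPM and Ddx3y at 111 to 178 CPM in all 12 libraries. Immunoglobulin RNA stood out in ko CL 2, with Ighm at 2575 CPM and Jchain at 314.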
